A study of Drosophila melanogaster with 3 samples.

How the data were processed

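ChIP-seq was performed on 3 biological replicates, with 1 library each, of whole white prepupae expressing GFP-tagged Sox14, from chromatin sonicated to 200 to 800 bp, per the labels. No control library was analysed here, although a control file entered the authors' peak calls, per the deposited text descriptions. The authors deposited, for builds dm6 and dm3, a relaxed list of 30000 peaks per replicate, a relaxed list for the pooled replicates, and an optimal list passing a threshold on the irreproducible discovery rate (IDR), per the same descriptions. The aligner, peak caller and IDR threshold are not given in the sources used here. Each peak had a signal from the authors' peak caller, on a scale of its own in each list, and the authors' −log10 q value. The signal was used only to rank peaks within a list. In dm6 every optimal peak was also in the pooled list, and the 9316 optimal peaks were exactly the 9316 of highest signal there. Since every relaxed list holds the same fixed number of peaks, its length says nothing about a replicate's yield. Relaxed lists include background by design, and 45.6% of the pooled peaks had a q value under 0.01. Read depth is unknown, so no interval covers sequencing error, and Wilson intervals cover the counting of peaks or genes only.

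Peak positions fitted the arm lengths of the Release 6 genome, and the dm6 lists were used with RefSeq sequence of that release and Ensembl release 115 genes (BDGP6.54). The dm3 lists were used only for counts within that build. Peaks were ranked by signal, and summits within 100 bp were taken as shared. Pairs of replicates were compared over their 9316 highest peaks, with 100 circular shifts per pair giving the chance level. Optimal peaks were compared with the 20684 pooled relaxed peaks outside the optimal list, that is, strong with weak peaks of 1 list, by Fisher's exact test for 6 arms and 7 annotation classes and by a permutation test with 100000 resamples for the distance to a TSS. Promoters were within 500 bp of any annotated TSS except those of transposable elements, followed in priority by 5′ UTR, 3′ UTR, coding exon, other exon, intron and intergenic sequence. Odds ratios given with Fisher's exact test and ratios of motif shares had 0.5 added to each count. The ratio for the heptamer AACAAAG at promoter summits had none added. All tests were two-sided with Benjamini-Hochberg adjustment within each family.

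The 24 gene lists were tested by Fisher's exact test for an optimal summit within 1 kb of a TSS, among protein-coding genes with any pooled relaxed summit in that window. The 14 motifs were sought on both strands in windows of 101 bp at summits and 1000 bp to the side, with the side alternating by rank, and compared by the exact McNemar test. The result of 1 gene list is not reported here, although the list stayed in the adjustment and in the counts of lists. Strong and weak optimal peaks were compared over 1000 peaks at each end of the ranking. Neighbouring peaks and genes are not independent, so p-values across them describe these lists rather than new animals. Named genes were the first 20 met down the optimal list by nearest protein-coding TSS, the 3 best-ranked members of each list and its first member in alphabetical order without a summit, and Sox14, Mical and Cul1, and not all of them are described. Lists, motifs, tests, this rule and most alternatives were fixed before the data were examined. The alternatives covered overlap distance, number of peaks, peak set, each replicate left out, background, window, matched lists, motif control, GC content, build and a separate IDR fit at 0.02. For arms, classes, TSS distance, gene lists and motifs, leaving out a replicate meant using the top peaks shared by the remaining pair. Those sets held 6655, 6771 and 6045 peaks without replicates 1, 2 and 3. A call that changed there cannot be laid to the replicate alone, since the set was also smaller and stricter. 2 Sox heptamers and the assignment of every summit to its nearest TSS were added after seeing the data.

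The statistics were tested on simulated data. A set overlap of 60.4% was recovered as 60.6%. Gene lists were simulated among the 7100 genes with a relaxed summit, 200 for each size and effect, and counted at an unadjusted p under 0.05. With no effect 12 lists of 3 genes, 6 of 10 and 7 of 20 passed. With the odds raised 4 times 0, 54 and 130 did, and with the odds lowered 4 times 66, 132 and 167, so a raised share in a list of 3 cannot be found. A gain of 8.43% planted in motif windows was returned as 8.43%, which shows only that planted words were found and does not test the comparison. Of 500 null draws of the motif test, 29 had p under 0.05. The permutation test gave 10 of 200 null draws under 0.05. The IDR fit put 4987 pairs under 0.02 where 6000 had been simulated as reproducible, so its count ran low there. The simulated reproducible share was smaller than the shares fitted to the data, so the shortfall in the data is not known. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.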

Results

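Binding sites of Sox14 were mapped in Drosophila melanogaster by chromatin immunoprecipitation and sequencing (ChIP-seq). Sox14 is a transcription factor of the Sox family, which binds DNA through an HMG box, and its gene responds to the moulting hormone ecdysone. The flies carried Sox14 fused to GFP at its C terminus, and chromatin was recovered with an antibody against GFP. Whole white prepupae, animals at the onset of metamorphosis, were used with males and females pooled, so each peak is an average over all tissues. The series held 1 group of 3 biological replicates, and its comparisons were therefore between replicates and between strong and weak peaks. Each replicate had a relaxed list of 30000 peaks, as did the pooled replicates, and the authors' optimal list held 9316 peaks. The sequencing depth is unknown because the lists give no read counts. All positions are on genome build dm6 unless another is named.

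The strongest optimal peak lay at the promoter of Sox14 itself (FBgn0005612). It spanned 23978250 to 23978829 on chromosome arm 2R, with its summit at 23978558, 243 bp upstream of the transcription start site (TSS). Its signal on the authors' scale was 3147, and it ranked 2, 3 and 4 in replicates 1, 2 and 3. A pair of far weaker optimal peaks lay in the Sox14 intron, with summits at 23980808 and 23981074 and signals of 124 and 146. The weaker of these had no summit within 100 bp in replicate 2.

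**Figure D1:**
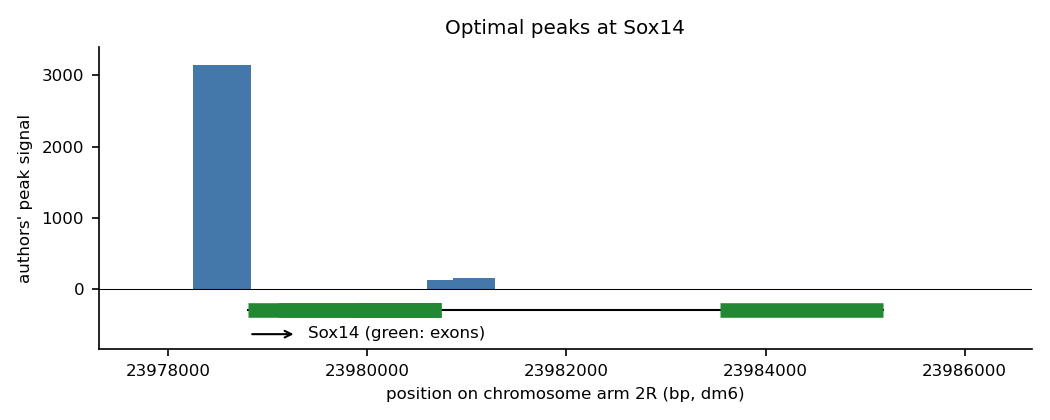
Optimal peaks at Sox14 on chromosome arm 2R, with position in bp on dm6 on the horizontal axis and the authors' peak signal on the vertical axis. Bars span each peak interval, green boxes are exons and the arrow gives the direction of transcription; the promoter peak reached 3147 and the intronic peaks 124 and 146.

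The next strongest peaks, with signals from 3123 down to 1999, were assigned to the protein-coding gene with the nearest TSS. They lay at CG14100 (summit 19590623 on 3L, 99 bp from the TSS), Ugalt, a UDP-galactose transporter (2703893 on X, 41 bp), and PNPase, a polynucleotide phosphorylase (31404662 on 3R, 78 bp). Promoter peaks of the same order were found at larp, an RNA-binding protein (339 bp), Chro, a chromodomain protein (86 bp), CenG1A (117 bp), CG18549 (110 bp), CG9147 (3 bp), CG1888 (224 bp), Tcs5 (110 bp) and Art3, an arginine methyltransferase (127 bp). Farther from the nearest protein-coding TSS were the peaks assigned to cbt (1388 bp), CG11050 (1029 bp), Lk6, a protein kinase (983 bp), CG4496 (555 bp), CG9663 (946 bp) and CG4004 (5094 bp). The most distant were those of CG13323, whose peak at 13035342 on 2R was intergenic and 11914 bp away, and osa, a subunit of a SWI/SNF chromatin remodelling complex, whose peak at 17704409 on 3R was 13941 bp away. The osa peak lay in an exon outside UTRs and coding exons, and which gene that exon belongs to was not examined. In all, 15 of the 20 genes had the summit within 1 kb of a TSS, and all 20 peaks ranked in the top 100 of every replicate. The lists do not show which gene a peak acts on.

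Mical and Cul1, reported targets of Sox14 in the pruning of neuronal processes, both carried optimal peaks, with ranks from 3089 to 7443 of 9316. The Mical promoter peaks ranked lowest of these, at 6961 and 7443. Mical, on arm 3R from 10001554 to 10042895, had promoter summits at 10042941 and 10043225 with signals of 118 and 111, and an intronic summit at 10039401 with a signal of 209. Each of its promoter peaks was among the top 9316 of 2 replicates, and the intronic peak was among those of all 3. Cul1, on arm 2R from 7916856 to 7921579, had a summit 294 bp upstream of a TSS at 7916562 with a signal of 216 and rank 3089, found in all 3 replicates. A second Cul1 promoter summit at 7917384 had a signal of 138 and was among the top peaks of 2 replicates.

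The replicates were compared to ask how far the same sites were recovered. Of the 9316 highest peaks of each replicate, 69.7% ± 4.19 (SD, n = 3 pairs) had a summit within 100 bp in another replicate. Replicates 1 and 2 shared 64.9%, replicates 1 and 3 shared 72.7%, and replicates 2 and 3 shared 71.4%. Shifting the peaks around each chromosome arm gave a mean of 1.41% and at most 1.79% in 100 shifts per pair. Across optimal peaks found in both replicates of a pair, Spearman's correlation of the signal ranks was 0.613 for replicates 1 and 2, 0.764 for replicates 1 and 3 and 0.753 for replicates 2 and 3. These correlations run across peaks, which are not independent replicates and were selected for agreement between the same replicates. Replicates 1 and 2 were thus the least alike pair by both measures.

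Of the 9316 optimal peaks, 5460 were among the top peaks of all 3 replicates (58.6%, 95% Wilson interval 57.6 to 59.6%). Another 2641 were among the top peaks of 2 replicates, 1103 of 1 replicate, and 112 of none. In the full relaxed lists, 86.9% had a summit in all 3 replicates. Of the 1000 strongest optimal peaks 98.8% were in the top peaks of every replicate, against 2% of the 1000 weakest (95% Wilson interval 1.3 to 3.07%). The weakest lie at the limit that defines the top peaks, which lowers their share by construction. Optimal peaks were also selected from the pool of these same replicates for signal and agreement. All these shares are therefore partly fixed by that selection and are not independent evidence of reproducibility. In the full relaxed lists the shares were 98.8 and 73% (95% Wilson interval 70.2 to 75.7% for the weakest).

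**Figure D2:**
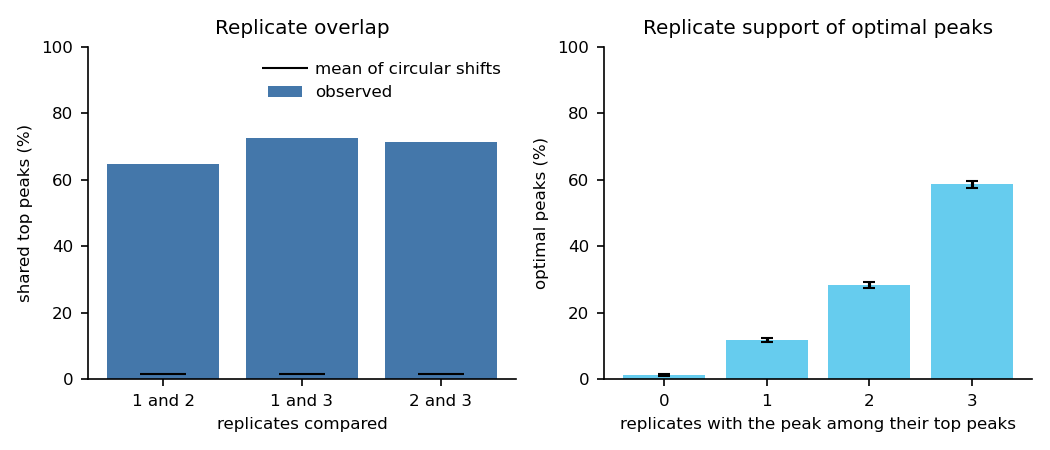
Left, percent of the 9316 highest peaks shared within 100 bp by each pair of replicates (bars), with the mean of 100 circular shifts as black lines; the bars stand between 64.9 and 72.7% and the lines near 1.41%. Right, percent of optimal peaks among the top peaks of 0 to 3 replicates, with 95% Wilson intervals; 58.6% were found in all 3.

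Optimal peaks were concentrated at promoters. Summits within 500 bp of an annotated TSS made up 43.8% of the optimal peaks (95% Wilson interval 42.8 to 44.8%), 24.5% of the other relaxed peaks and 13.6% of random positions. Against the other relaxed peaks the odds ratio was 2.4 (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 1.34e-239). Introns held 39.1% of optimal summits against 47.5% of other relaxed summits (exact adjusted p = 3.92e-41), and intergenic sequence 14.4% against 22.7% (exact adjusted p = 6.22e-65). Relative to random positions, where introns made up 39.3%, the intron share did not differ (exact adjusted p = 0.911). Coding exons held 0.258% of optimal summits against 1.29% of other relaxed summits and 13.1% of random positions, and 3′ UTRs held 0.719% against 1.96%. The shares in 5′ UTRs (0.805 and 0.919%) and other exons (0.923 and 1.13%) did not pass the test (adjusted p = 0.351 and 0.133 by Fisher's exact test). The 5′ UTR share was lower and passed with a replicate left out (exact adjusted p = 0.0344 without replicate 1, 0.0016 without replicate 2 and 0.0238 without replicate 3). With every replicate kept, it also passed in the upper part of the list by signal (exact adjusted p = 0.0472) and among peaks in all 3 replicates (0.00201). The median distance from a summit to the nearest TSS was 768 bp for optimal and 2138 bp for other relaxed peaks (permutation test, two-sided, 100000 resamples, p = 1e-05, the smallest it can give).

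Across the chromosome arms, optimal peaks were close to 70 per Mb on every large arm, from 67.3 on 2R to 72.5 on 3L, with 70.2 on X. The small chromosome 4, which is largely heterochromatic, held 30 optimal peaks, or 22.3 per Mb. Its share of 0.322% against 0.454% of other relaxed peaks did not pass (exact adjusted p = 0.179), but did without replicate 1 (0.00629) and without replicate 3 (0.0358). With every replicate kept, it passed in the upper part of the list by signal (exact adjusted p = 0.0361) but not among peaks in all 3 replicates (0.094). Compared with the other relaxed peaks, 2R held a larger share of optimal peaks (18.3% against 16.6%, odds ratio 1.12, adjusted p = 0.00134 by Fisher's exact test) and X a smaller one (17.7% against 19.96%, odds ratio 0.865, adjusted p = 3.91e-05). With arm length as the reference, neither 2R (ratio 0.967, exact adjusted p = 0.256) nor X (ratio 1.01, exact adjusted p = 0.683) stood apart, while chromosome 4 fell to 0.32 of its share (exact adjusted p = 1.25e-13).

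Genes were then asked whether an optimal summit lay within 1 kb of a TSS, in 24 gene lists. Of 13945 protein-coding genes, 4677 (33.5%) had one. Among the 7100 genes with any relaxed summit in that window, the background of the test, the share was 65.9%. After adjustment over the 24 lists, autophagy and cytoplasmic ribosomal protein genes had a larger share than other genes, and cuticle protein and chemoreceptor genes a smaller one.

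All 19 autophagy genes in the background had an optimal summit (100%, 95% Wilson interval 83.2 to 100%, adjusted p = 0.00261 by Fisher's exact test). The highest ranked were Atg18a (signal 528, 68 bp from the TSS), Atg7, which encodes an enzyme that activates Atg8 and Atg12 (signal 419), and Atg17 (signal 419, 292 bp), while Atg10 had none. This call held under 4 of 11 alternatives. With the full optimal list it was lost within 500 bp (exact adjusted p = 0.112) and within 5 kb of a TSS (0.0832). It was also lost in the upper part of the list by signal (0.478) and among peaks in all 3 replicates (0.911). In the smaller sets of top peaks shared by a pair of replicates it was lost too. There the log2 odds ratio of 4.34 became 0.94 without replicate 1 (exact adjusted p = 0.377), 1.51 without replicate 2 (0.13) and 0.000304 without replicate 3 (1). No autophagy gene in the background lacked a summit, so the 4.34 was finite only through the 0.5 added to each count. Of 75 ribosomal protein genes, 64 had an optimal summit (85.3%, odds ratio 2.93, adjusted p = 0.00239 by Fisher's exact test), led by RpS19b (signal 999), RpL7 (660) and RpL34b (491), and RpL10 had none. That call held under 7 of 11 alternatives and was lost without replicate 1 (exact adjusted p = 0.0734) and without replicate 3 (0.166), where the log2 odds ratio of 1.55 fell to 0.88 and 0.76. With every replicate kept, it was also lost in the upper part of the list by signal (exact adjusted p = 0.0825) and among peaks in all 3 replicates (0.0799).

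Of 18 cuticle protein genes in the background, 4 had an optimal summit (22.2%, 95% Wilson interval 9 to 45.2%, adjusted p = 0.00239 by Fisher's exact test), among them Cpr72Eb (signal 378), Cpr62Ba (293) and Cpr49Ah (122). Most of the 115 cuticle genes had no relaxed summit at all near a TSS, and 3.48% of them had an optimal one. Of 10 odorant and gustatory receptor genes, only Gr63a, part of a carbon dioxide receptor, had an optimal summit (signal 225, odds ratio 0.0815, adjusted p = 0.00261 by Fisher's exact test). The cuticle call held under 10 of 11 alternatives and the receptor call under 6 of 11. The receptor call was lost without replicate 1 (exact adjusted p = 0.0734), replicate 2 (0.115) or replicate 3 (0.454), where the log2 odds ratio of -3.62 became -2.78, -2.20 and -1.62. With every replicate kept, it was also lost in the upper part of the list by signal (exact adjusted p = 0.272) and among peaks in all 3 replicates (0.16). All 4 of these calls held against random lists matched on gene length and number of TSSs (permutation adjusted p = 0.0186 for autophagy, 0.00768 for ribosomal proteins, 0.0321 for cuticle and 0.00936 for receptors).

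The ecdysone-responsive regulators had an optimal summit in 18 of 20 genes (90%, 95% Wilson interval 69.9 to 97.2%), which did not pass the adjusted test against genes with a relaxed summit (adjusted p = 0.106 by Fisher's exact test). Against all protein-coding genes the same 90% stood beside 33.5% overall and passed (exact adjusted p = 1.5e-06). In all, the list passed under 5 of 11 alternatives. The others were the upper part of the optimal list by signal (exact adjusted p = 0.0096), within 5 kb of a TSS (0.0188), gene bodies plus 1 kb (0.00584) and the nearest TSS, added after seeing the data (0.00194). It did not pass with any 1 replicate left out (exact adjusted p from 0.115 to 0.194) or against matched lists (permutation adjusted p = 0.178). After Sox14, the highest ranked were E23, an ABC transporter that dampens the ecdysone response (signal 864, 202 bp from the TSS), and Eip75B, a nuclear receptor (signal 679, 34 bp, with 6 optimal summits within 1 kb of its TSSs), and Hr38, another nuclear receptor, had none. Of the other ecdysone-inducible genes 5 of 9 had a summit (adjusted p = 0.633 by Fisher's exact test), with Eip63F-1 (signal 423), ImpE2 (246) and Eip63E (245) the highest, and of the genes of ecdysteroid synthesis and clearance 3 of 6 (exact adjusted p = 0.563), namely mld (515), Start1 (197) and shd, the last hydroxylase of ecdysone activation (146).

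The lists for apoptosis, neurite pruning, Notch, the proteasome and the Sox family did not pass among genes with a relaxed summit. Apoptosis genes had a summit in 10 of 13 (76.9%, exact adjusted p = 0.674), with the death activator hid (signal 859), its target Diap1 (713) and the initiator caspase Dronc (488) at the top and none at Damm. Neurite pruning genes had one in 11 of 15 (73.3%, exact adjusted p = 0.857), led by SkpA (722), the receptor wit (339) and IKKepsilon (308), and bsk had none. Notch pathway and E(spl) genes had one in 11 of 14 (78.6%, exact adjusted p = 0.563), led by fng (743), and proteasome genes in 20 of 27 (74.1%, exact adjusted p = 0.563), led by Rpn5 (452). In the Sox family, 4 of 6 genes had a summit (exact adjusted p = 1), including Sox102F (314) and D (266). Against all protein-coding genes, of which 33.5% had a summit, larger shares passed for apoptosis (66.7%, exact adjusted p = 0.0241), neurite pruning (64.7%, 0.0225) and Notch and E(spl) genes (61.1%, 0.0398). These 3 lists passed under none of their other 10 alternatives, where exact or permutation adjusted p reached 0.742, 1 and 1.

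Lists of patterning and of single tissues did not pass the adjusted Fisher test. Homeotic and segmentation genes had an optimal summit in 4 of 13 (30.8%, exact adjusted p = 0.071), all weak, with en (signal 120), wg (113) and Dfd (103) the highest. Their lower share passed under 5 of 11 alternatives, among them without replicate 2 (exact adjusted p = 0.0109) and without replicate 3 (0.00696). Against matched lists it also passed, as did the lower share of neuron genes (permutation adjusted p = 0.0321 each). Imaginal disc patterning genes had one in 13 of 23 (56.5%, exact adjusted p = 0.563), led by so (237). Neuron genes had one in 3 of 10 (exact adjusted p = 0.106), although elav, an RNA-binding protein of neurons, ranked 226 with a signal of 841. Fat body genes had one in 8 of 11 (exact adjusted p = 0.857), with Lpin, a phosphatidate phosphatase, at rank 88 and a signal of 1217. Muscle genes had one in 3 of 7 (exact adjusted p = 0.442), led by sls (359), and hemocyte genes in 1 of 4 (exact adjusted p = 0.236), the scavenger receptor crq (252). Midgut genes had one in 3 of 6 (exact adjusted p = 0.563) and testis genes in 3 of 5 (exact adjusted p = 1). No salivary gland secretion gene (0 of 3, exact adjusted p = 0.106), antimicrobial peptide gene (0 of 3, exact adjusted p = 0.106) or eggshell and yolk gene (0 of 2, exact adjusted p = 0.236) had one, and with so few members these shares allow up to 56.1, 56.1 and 65.8% (95% Wilson intervals). The salivary gland list passed as lower under 4 of 11 alternatives, over which exact or permutation adjusted p ran from 0.00313 to 0.618. These were within 5 kb of a TSS (exact adjusted p = 0.00313), gene bodies plus 1 kb (0.0363), all protein-coding genes (0.0109) and the nearest TSS (0.0381). Against all protein-coding genes, and under no other alternative, testis (11.1%, exact adjusted p = 0.0262), antimicrobial peptide (0%, 0.0109) and eggshell and yolk genes (0%, 0.00271) also passed as lower.

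**Figure D3:**
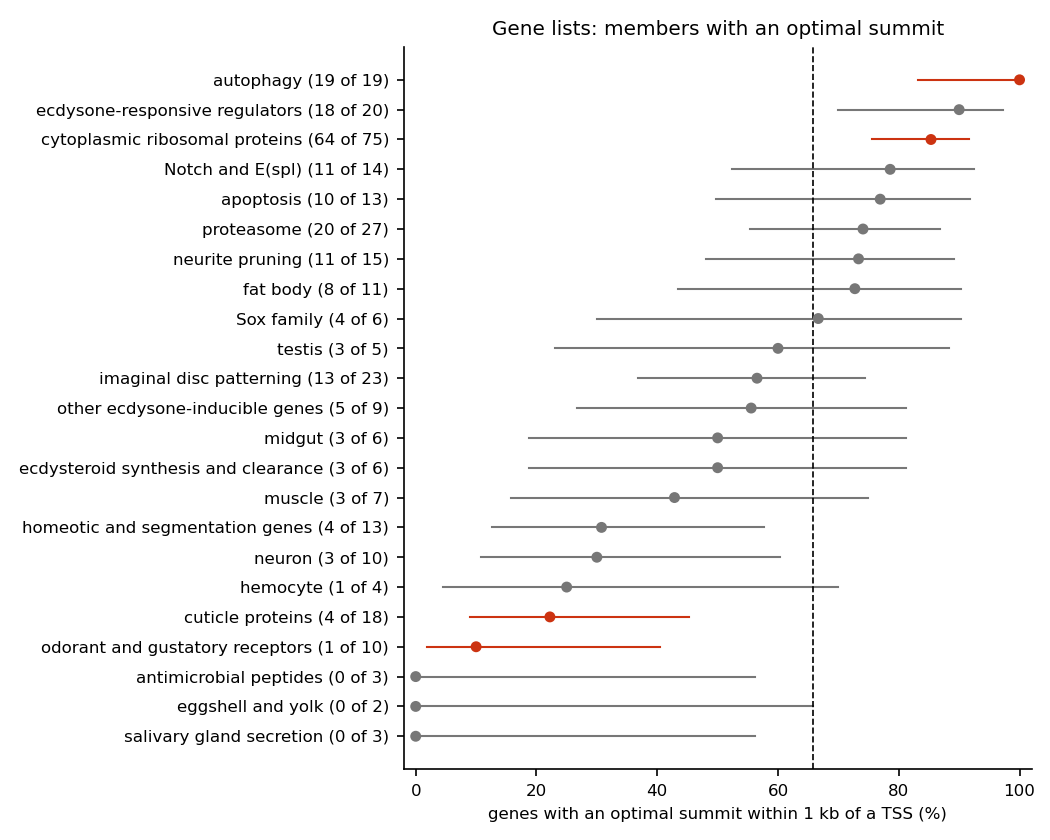
Percent of each reported list's genes with an optimal summit within 1 kb of a TSS, among genes with any relaxed summit there, with 95% Wilson intervals and the counts in brackets. The dashed line is the share over all such genes (65.9%), and red marks lists with an adjusted p under 0.05, which are autophagy, ribosomal proteins, cuticle proteins and receptors.

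Sequence at the summits was compared with windows 1 kb to the side for 14 consensus motifs. The Sox consensus WWCAAWG occurred within 50 bp of 18.8% of optimal summits (95% Wilson interval 18 to 19.6%) and in 14.4% of flanks (exact McNemar test, two-sided, adjusted p = 7.7e-15). Larger ratios were found for sites of promoter-bound factors. The site of DREF, a factor of housekeeping promoters, was at 1.73% of summits and 0.279% of flanks (ratio 6.09, exact adjusted p = 7.95e-24), and the core promoter element Motif 1 at 0.837% and 0.107% (ratio 7.48, exact adjusted p = 1.17e-13). Forkhead (29.4 against 24.2%, exact adjusted p = 7.7e-15), GATA (21.3 against 17.4%, adjusted p = 3.87e-11), TATA box (6.22 against 4.4%, adjusted p = 5.15e-08) and the Sox core ACAAT (28.4 against 24.6%, adjusted p = 1.39e-08) were also more frequent at summits. The E-box (36.3 against 41%, exact adjusted p = 7.77e-11) and the single RGGTCA site of the ecdysone receptor (3.54 against 5%, adjusted p = 1.37e-06) were less frequent at summits. GAGA factor (12.3 against 12.2%, exact adjusted p = 0.982), Zelda (1.15 against 1.37%, adjusted p = 0.224), AP-1 (1.07 against 0.988%, adjusted p = 0.657), Grainyhead (0.0966 against 0.225%, adjusted p = 0.0599) and the inverted repeat of the ecdysone receptor with Usp (0.0644 against 0.15%, adjusted p = 0.147) did not pass. GAGA was less frequent at summits without replicate 2 (exact adjusted p = 0.000649) and without replicate 3 (0.0247), and Zelda without replicate 1 (0.0124). GAGA was more frequent at summits in windows reaching 100 bp (log2 ratio 0.14, exact adjusted p = 0.000134). Against the other relaxed summits in place of flanks, the calls for ACAAT (exact adjusted p = 0.146), Forkhead, TATA box and RGGTCA (0.746 each) were lost, while those for WWCAAWG, GATA, E-box, DREF and Motif 1 held. In that comparison GAGA was less frequent at optimal summits (exact adjusted p = 0.0286).

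Summits were richer in A and T than flanks (63.4% ± 9.8, SD over 9316 windows, against 57.5% ± 10.6). Against dinucleotide-preserving shuffles of the same windows, the ratio for WWCAAWG was 1.09 (exact adjusted p = 0.00789) and that for GAGA 1.29 (9.49% of shuffled windows, exact adjusted p = 7.16e-11). The directions for ACAAT, E-box, GATA and TATA box turned over. The Sox core ACAAT was then less frequent at summits (ratio 0.879, exact adjusted p = 3.77e-09) and the E-box more frequent (1.11, 3.13e-07). GATA (0.946, exact adjusted p = 0.0636) and TATA box (0.983, 0.841) did not pass. Forkhead kept a ratio of 1.21 (exact adjusted p = 9.36e-16), DREF 10.4 (6.42e-31) and RGGTCA 0.795 (0.00328). Motif 1 was in 0% of shuffled windows (exact adjusted p = 4.63e-23). Between the 1000 strongest and the 1000 weakest optimal peaks, ACAAT was at 33.1 and 26.5% (adjusted p = 0.0103 by Fisher's exact test), Forkhead at 35.5 and 29.1% (adjusted p = 0.012) and GAGA at 8.4 and 13.6% (adjusted p = 0.00355). The Forkhead call was lost over 500 peaks at each end (log2 odds ratio 0.45, exact adjusted p = 0.12) and over 25% at each end (0.12, exact adjusted p = 0.396), where those for ACAAT and GAGA held. None of the 14 motifs passed within tertiles of GC content, where these 3 had permutation adjusted p = 0.37, 0.63 and 0.414.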

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

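The word AACAAAG was chosen after a count of short words at the summits had been seen, identical tRNA copies were counted after the tRNA share was known, and the tests of the word were moved to peaks left out of its choice after their values over all peaks were seen, while the other tests were set out before their results were seen. The design has 1 group, so no biological explanation was tested for any pattern.

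The dm3 lists held peaks outside the 6 chromosome arms, while the dm6 lists used in the comparisons held none there. The dm3 ones were flagged for exceeding the 3 that a count of 0 allows, which does not show that their number is unusual. Whether this sequence lies on the dm6 arms was not examined. There were 52 among the 30000 pooled relaxed peaks and 4 among the 9336 optimal peaks. The optimal ones lay on XHet, with summits at 84707 (signal 135) and 50274 (105), and on 3LHet, at 1395205 (111) and 2409801 (88), in dm3 coordinates.

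The Sox heptamer AACAAAG was found within 50 bp of 595 optimal summits (6.39%, 95% Wilson interval 5.91 to 6.9%) and in 3.17% of flanks (exact McNemar p = 3.56e-25), while AACAATG did not pass (2.51 against 2.26%, exact p = 0.293). AACAAAG was also at 4.81% of the other relaxed summits, a ratio of 1.33 (exact p = 2.86e-08), and at 6.6% of the 1000 strongest optimal summits against 5.4% of the 1000 weakest (exact p = 0.3). Since counts at these summits had picked the word, the choice was repeated on 4658 of the peaks among the 8 words of WWCAAWG, where AACAAAG came first (ratio 2.12), and tested on the other 4658. A rank among words of the same composition, set out with these tests, was dropped for that reason. There the tables argued against base composition as the whole cause, since shuffles that keep dinucleotides held the word in 3.18% of windows against 6.01% (ratio 1.89, exact p = 2.71e-11). Density within 25 bp of those summits over bands of 51 bp centred 100 bp away was 1.46 (95% exact interval 1.18 to 1.80). That is above the 1 of an even spread, but reaches below the 1.2 allowed in advance for sites placed without regard to the summit. Over all peaks, which had picked the word, it was 1.5 (95% exact interval 1.3 to 1.72) and passed that level, so the outcome changed with the split and a rise of up to 1.2 times stays open. Direct recognition by Sox14 is a hypothesis that these lists leave open, since other HMG-box proteins may bind the same word and most summits lack it.

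The strongest peak stood at the promoter of Sox14, the tagged gene. Extra genomic copies of the region in the tagged line would raise recovery over the whole locus. Within 20 kb of the Sox14 TSS there were 15 other relaxed summits against a median of 9 around 13944 other protein-coding genes, and 75.9% of genes had fewer. That lay between the levels set in advance for and against extra copies, and a count of summits does not measure copy number, so it decides nothing. The intronic optimal peaks of Sox14 had signals of 124 and 146 (ranks 6546 and 5320) against 3147 at its promoter. Extra copies would lift all of these alike, so this contrast argues against them as the whole cause of the promoter peak. How far they raised its signal and rank cannot be told without an untagged line or input signal.

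Promoter peaks may include recovery of highly transcribed loci without Sox14 binding. Of the peaks left out of the word's choice, 2054 summits within 500 bp of a TSS held AACAAAG in 5.94% of windows against 3.26% of flanks (ratio 1.82, 95% interval 1.39 to 2.47 from 2000 resamplings of peaks), which excludes a promoter set wholly without the word's enrichment and leaves open the many summits lacking it. Ribosomal protein genes had optimal summits at 64 of 75 (log2 odds ratio 1.55, matched permutation adjusted p = 0.00768, but 0.88 without replicate 1 and 0.76 without replicate 3, where the call was lost). That would go with recovery of such loci, but transcription was not measured. The sites of DREF and Motif 1 (ratios 6.09 and 7.48 over flanks) decide nothing, since any set rich in promoters could show them. Against other relaxed summits their ratios were 2.38 and 2.83. They were at 0.5 and 0.4% of the 1000 strongest optimal summits and 1.6 and 1.1% of the 1000 weakest, and neither difference passed. Of 290 tRNA genes 21.4% had an optimal summit within 1 kb against 33.5% of protein-coding genes (odds ratio 0.542, exact p = 9.33e-06). That level had been set against such recovery, but 238 of the 290 tRNA genes (82.1%) have an identical copy, and reads that map to several places could lower their share. The tRNA and protein-coding genes were also not matched on number of TSSs. With the tRNA genes, recovery of transcribed loci therefore cannot be told apart from binding, and it stays open for promoter summits with or without the word.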

How the results depend on the processing

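The motif words AACAAAG and AACAATG and the nearest-TSS assignment were added after seeing the data. The promoter excess and the shorter distance to a TSS kept their direction and passed under every alternative run. Of 515 alternatives for single arms, classes, reported lists, motifs and rank trends, 396 kept direction and side of the threshold, and 28 lost and 34 gained the call in the same direction. The other 57 turned direction, 11 with a call in the main setting or the alternative and 46 with a call in neither. The causes were not tested. Mean overlap of replicates was 55.3% within 50 bp, 76.3% within 200 bp, 79.2% by 1 bp of interval overlap, 77.5% over the top 1000 and 63.3% over 2 times as many peaks, and leaving out a replicate gave 64.9 to 72.7%. Optimal peaks in all replicates were 44% within 50 bp and 65.1% within 200 bp, and with a replicate left out 64.2 to 70.3%, which needs fewer replicates to hold the peak. Mean rank correlation without a replicate ran from 0.613 to 0.764. The IDR fit gave 5263 matched peaks for replicates 1 and 2, 6954 for 1 and 3 and 6741 for 2 and 3, beside 9316 optimal peaks. The optimal peaks are pooled ones at a threshold not given in the sources used here, so the counts are not of the same kind. With arm length as background 1 arm passed rather than 2, and the log2 ratios turned to -0.048 for 2R and 0.013 for X. In place of 4 gene lists, 2 passed in the upper part of the optimal list by signal (ecdysone-responsive regulators and homeotic genes, none of the 4), 2 among peaks in the top of all 3 replicates (cuticle and homeotic), 1 to 3 with a replicate left out (cuticle each time, homeotic without replicates 2 and 3, ribosomal proteins without replicate 2), 7 with gene bodies plus 1 kb and 13 against all protein-coding genes, where genes without any relaxed summit enter. Against dinucleotide shuffles the log2 ratios turned to -0.19 for ACAAT and 0.15 for the E-box, both called, and to -0.0799 for GATA and -0.0247 for the TATA box, neither called there. For GAGA factor (log2 ratio near 0) it was -0.25 in the upper part of the list, -0.22 among peaks in all 3 replicates and -0.12 against other relaxed summits, all called. With a replicate left out it ran from -0.24 to 0.0863, called without replicate 2 and without replicate 3. In the other direction, GAGA gave 0.14 within 100 bp and 0.37 against shuffles, both called. The turns without a call follow as log2 values. With arm length as background they were 0.042 for 2L, 0.059 for 3L and -0.015 for 3R, and against random positions 0.16 for other exons. In the upper part of the list they were 0.025 for 2L, 0.55 for the Sox family, 0.85 for other ecdysone-inducible genes, -0.73 for fat body and -0.18 for proteasome. Among peaks in all 3 replicates they were 0.039 for 2L, 0.29 each for the Sox family and ecdysteroid synthesis, -0.098 for Notch and -0.083 for AP-1. With a replicate left out the ranges were -0.00745 to 0.0498 for 2L, -1.01 to 0.016 for other ecdysone-inducible genes, -0.27 to 0.14 for ecdysteroid synthesis, -0.27 to 1.02 for the Sox family, -0.032 to 0.62 for fat body, -0.27 to 0.27 for Notch, -1.10 to 0.36 for EcR-Usp and -0.21 to 0.12 for AP-1. The Sox family gave 0.77 within 5 kb, 0.95 with gene bodies, 0.99 against all genes and 1.71 by nearest TSS, and imaginal disc genes 0.14, 0.89 and 1.21 under the last 3. Other ecdysone-inducible genes gave 1.34 with gene bodies and 0.97 by nearest TSS, where homeotic genes gave 0.88 and midgut 0.23. AP-1 was -0.058 within 25 bp and -0.041 against other relaxed summits, and shuffles gave 0.24 for EcR-Usp and 1.44 for Grainyhead. Rank trends turned to 0.55 for RGGTCA and 0.64 for AP-1 over 500 peaks at each end, to 0.16 for Zelda over 25% at each end, and to -0.015 for GATA and -0.18 for the TATA box within GC tertiles. Within GC tertiles 0 rank trends passed rather than 3, and the Forkhead trend also lost its call over 500 peaks and over 25% at each end. No paired analysis was possible because there is a single group. Depth is unknown and sets no limit that can be stated.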

Other observations

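Several long genes held many optimal summits inside their span, counted after the peak positions were seen. The highest counts were 31 in kirre, a cell adhesion gene of 394 kb on X, 28 in Eip75B, an ecdysone-responsive nuclear receptor of 114 kb on 3L, 25 in sbb (79.1 kb) and 23 in shn, a zinc finger protein of Dpp signalling (58.3 kb). Next were CG1677 and ush with 22 each, Snoo with 21 and Tet with 20. Per kb these came to 0.0787 for kirre, close to the 0.0696 over all arms, 0.246 for Eip75B, 0.316 for sbb and 0.394 for shn.

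Several classes of genes that do not encode proteins carried optimal summits within 1 kb of a TSS less often than the 33.5% of protein-coding genes. A gene with more annotated TSSs had more windows. These shares were not matched on number of TSSs or limited to genes with a relaxed summit. The share was 19.4% of 3261 ncRNA genes (exact adjusted p = 3.69e-59), 26% of 269 snoRNA genes (exact adjusted p = 0.0108) and 7.46% of 268 pseudogenes (exact adjusted p = 1.9e-23), while the 18.8% of 32 snRNA genes did not pass (exact adjusted p = 0.0913). Annotated transposable elements made up 5.93% of the arm sequence and held 17 optimal summits (0.182%) and 82 other relaxed summits (0.396%, odds ratio 0.47, exact p = 0.00219). Reads that map to several places are commonly dropped, and how the authors treated them is not given in the sources used here.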
